A study of Homo sapiens with 8 samples.

How the data were processed

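Pancreas tissue of 8 donors, about 40 mg each, was profiled by single-nucleus multiome (10x Genomics). Per the labels, nuclei were stained with 7-aminoactinomycin D and sorted to 120000, and 18300 nuclei entered each reaction. Each library was read with Cell Ranger ARC 2.0.0 on the hg38 build, per the submitters' processing notes. The deposited values of libraries 2, 4 and 6 were raw counts, that is RNA UMIs per gene and ATAC counts per peak for every barcode. The deposited barcode and feature lists of all 8 libraries were of another kind, with no values, and were used for the peak positions. The peaks differed between lists, so they had been called per library. Aligner settings and the gene annotation release are not given in the sources used here. ATAC values were mostly even numbers, as when the cut sites at both ends of a fragment are counted, and odd values made up 15.0, 19.4 and 16.6% in libraries 2, 4 and 6. The feature lists of libraries 3, 5 and 8 had 1, 1 and 2 empty lines, and these lines were not used.

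Nuclei were called among 409005, 552532 and 641590 barcodes as those with at least 500 UMIs, 300 genes and 1000 ATAC counts and at most 10% mitochondrial UMIs. The called nuclei were 5.69, 15.7 and 12.9% of the input and held 71.4, 87.6 and 81.6% of UMIs. A further 894, 333 and 279 barcodes had enough UMIs but too few ATAC counts, and the mitochondrial limit removed 3, 1 and 16. Doublets were found with scrublet in scanpy 1.11.5 at an expected rate of 0.06 and removed, 14, 21 and 167 in libraries 2, 4 and 6. Peaks of the 3 libraries on autosomes that overlapped by at least 1 base were merged into 129749 regions. The 52854 regions with a peak in each of the 3 libraries were used, and they held 94.4, 85.6 and 87.1% of the ATAC counts.

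RNA was clustered on 2000 variable genes scaled within each library, and ATAC on term-frequency weighted presence over the regions, centred within each library. Both used 30 components, 15 neighbours and Leiden clustering at resolution 1 (leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0). Clusters were named from 15 marker lists fixed before the data were examined, as were the comparisons, tests, gene lists and most alternatives. They covered acinar, ductal, endocrine, beta, alpha, delta, gamma, stellate, endothelial, macrophage, T/NK cell, B/plasma cell, mast, Schwann and adipocyte markers. The best-scoring list gave the name, with a pseudocount of 5 CPM, where at least 3 of its markers were seen in 10% of nuclei and were 2-fold above the reference level. A cluster stayed unnamed where its 10 leading genes held more markers of another class, or where it had low depth and no marker of its own there. No cluster scored best for adipocytes. Names carry "-like" because no other source gave the cell type of a nucleus.

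RNA was compared between classes drawn from ATAC clusters, and ATAC between classes drawn from RNA clusters. The tested counts thus did not form the clusters. The names of ATAC clusters also came from RNA, which decided which of them were joined into a class or left unnamed. Counts were summed per library and class, and a class entered with at least 20 nuclei. The sums of acinar-like nuclei held 3641899, 7712596 and 3853344 UMIs in libraries 2, 4 and 6, and those of ductal-like nuclei 406648, 993582 and 1142449. Endocrine-like sums held 119381, 78804 and 238537 UMIs, stellate-like sums 381834, 671139 and 932398, macrophage-like sums 227866, 586454 and 562883, and endothelial-like sums 144681 and 150640 in libraries 4 and 6. All classes shared a fit in edgeR 4.0.16 (R 4.3.3) with the quasi-likelihood test, TMM scaling, filterByExpr, donor as a block and Benjamini-Hochberg adjustment over the features of a comparison. A call had an adjusted p under 0.05. The fixed markers, XIST and Y-linked genes stayed out of the RNA tests, and sex chromosomes out of the ATAC tests. Both classes of a comparison came from the same donors, which makes pairs. As a check, acinar-like and ductal-like sums of the same library correlated at 0.258, 0.340 and 0.288 in RNA and at 0.110, 0.120 and 0.137 in ATAC after class means were removed.

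The 14 gene lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over 56 list and comparison pairs, and again with an estimated correlation. The lists were also tested with fry of the same package. They covered digestive enzymes and secretory proteins, ductal ion and fluid transport, exocrine transcription factors, islet transcription factors, hormone secretion machinery, the ER stress and unfolded protein response, MHC class I, MHC class II, interferon response, type 1 diabetes risk locus genes, extracellular matrix and fibrosis, immediate early and stress genes, ribosomal protein genes, and angiogenesis and endothelial signalling. The fixed cell type markers were left out of the lists. In 7 list and comparison pairs the median, mean and test differed in sign, with camera adjusted p from 0.345 to 0.982.

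Genes named in the text followed a rule: up to 8 per direction with the largest fold change among calls with a mean of at least 20 CPM and the same direction in every library with both classes, and up to 3 members per list with the smallest adjusted p. Clone, LINC, MIR, antisense and mitochondrial genes were left out. For ATAC the rule took up to 3 regions per direction and the start-site regions of genes that mark cell types, where tested. CPA1, PRSS1, CFTR, KRT19, COL1A1, PDGFRB and PECAM1 were also fixed markers whose RNA named the classes. Their start sites are therefore no independent support for the class names. Exceptions chosen after their values were seen are stated as such. Not all genes under the rule are printed. A fold against a class with no counts is a lower bound at a floor of 3 counts over the class, and with 1 to 3 counts the ratio is given with its exact interval. Both pool counts over the libraries in which each class entered and are not paired by donor. Intervals and floors cover counting error only.

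Gene positions came from a RefSeq table of assembly GRCh38.p14, the assembly behind hg38, which matched 22978 of 36601 genes by symbol and 720 by an older symbol. The table gives no strand, so a region counted as lying at a gene end when within 1 kb of either annotated end of a protein-coding gene, a departure from the planned start sites. For 17 genes named by the rule the strand was written by hand, and their start sites are true starts. The share of peaks near gene ends was compared between peaks overlapped in every other list and peaks overlapped in none with an exact 2-sided sign-flip permutation test (scipy 1.17.1). Correlation of accessibility and RNA used 1 region per gene, the one with the highest mean count. Free RNA was measured in barcodes with 5 to 50 UMIs, and its share in a sum was limited from above by markers of other classes. The limits were 2.71, 0.848 and 1.50% in acinar-like sums of libraries 2, 4 and 6, 3.67, 7.41 and 1.94% in ductal-like sums and 4.55, 1.58 and 2.65% in endocrine-like sums.

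The tests were run on simulated counts with 200 changed features. Of features changed 4-fold, edgeR recovered 49 of 64 in the RNA comparison of acinar-like and ductal-like nuclei, 10 of 65 for stellate-like and endothelial-like, 27 of 58 for endocrine-like and acinar-like, and 24 of 64 for macrophage-like and stellate-like nuclei. In ATAC the numbers were 42 of 61, 31 of 62, 16 of 65 and 41 of 61. Of RNA changes of 2-fold between acinar-like and ductal-like nuclei 9 of 60 were recovered, and of 1.5-fold 0 of 62. Calls in the data were far more numerous than the 200 features changed here, which makes the adjustment less strict. The simulated rates therefore do not measure how often small changes were detected in the data. Over all simulated folds, unchanged features made up 8 of 66 calls in RNA for acinar-like and ductal-like nuclei, 2 of 12 for stellate-like and endothelial-like, 3 of 33 for endocrine-like and acinar-like, and 0 of 25 for macrophage-like and stellate-like nuclei. In ATAC they made up 4 of 61, 2 of 41, 0 of 24 and 1 of 53 calls. In 3 of the 4 RNA comparisons and in ATAC between acinar-like and ductal-like nuclei this share was above the 0.05 set for a call, from few simulated calls. Alternatives were DESeq2 1.42.0, library size without TMM, no filter, only the compared classes in the fit, no block, stricter nuclei, doublets kept, at least 50 nuclei, Leiden resolution 2, clusters of each library alone, each library left out in turn and classes from the tested modality. Free RNA was also subtracted, its 50 leading genes left out, and regions limited to peaks with reciprocal overlap. Peak shares were recomputed within 5 kb, with that overlap rule and for peaks of at least 500 bases. Chosen after the data were seen were the floor of 10 nuclei for endocrine-like and for endothelial-like nuclei, the comparison of macrophage-like and stellate-like nuclei, shares without the unnamed class, and the splits of the sums. The planned alpha-like against beta-like comparisons were not made, because all endocrine-like nuclei formed 1 cluster, and no comparison between donors was made.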

Results

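The material was human pancreas from 8 donors, 1 library each, and all 8 formed a single group. Each library was a single-nucleus multiome, an assay that reads RNA and open chromatin (ATAC) from the same nucleus. The series concerns gene regulation in the human pancreas during progression to type 1 diabetes, but the labels gave no clinical status per donor, so no donors were set against each other. Nuclear RNA and ATAC counts were analysed in libraries 2, 4 and 6, and peak lists in all 8. The RNA totals were 7647639, 12338594 and 10047581 unique molecules (UMIs) in libraries 2, 4 and 6, and the ATAC totals were 13953551, 66175013 and 40261135 counts. Nuclei numbered 1042, 2880 and 2368, with median depths of 3353, 3590 and 3127.5 UMIs and 8048, 21506 and 14835 ATAC counts. The peak lists held from 63542 to 141128 peaks per library on the hg38 build.

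The first question was which cell classes of exocrine, endocrine, stromal, vascular and immune tissue the nuclei represented. Acinar-like nuclei, named from digestive enzyme genes, were the most frequent class in each of the 3 libraries, at 45.6% in library 2 (42.5 to 48.7), 65.6% in library 4 (63.8 to 67.4) and 53.1% in library 6 (51.0 to 55.2). Brackets after shares hold exact 95% binomial intervals. Ductal-like nuclei made up 7.98, 11.5 and 14.1% in libraries 2, 4 and 6, and stellate-like nuclei, the matrix-producing mesenchymal class, 3.79, 7.38 and 9.81%. Macrophage-like nuclei made up 4.96, 6.51 and 8.36%, and T/NK cell-like nuclei 0.681% in library 2 (0.274 to 1.40), 4.16% in library 4 (3.46 to 4.96) and 6.45% in library 6 (5.46 to 7.56). Endothelial-like nuclei numbered 16, 81 and 65, and endocrine-like nuclei 19, 17 and 64. B/plasma cell-like nuclei reached 1.32% in library 6, Schwann-like nuclei 0.389% in library 2 and mast-like nuclei 0.560% in library 4. No mast-like nucleus was among the 1028 of library 2, which allows a share of up to 0.292% at a limit of 3 counts. An unnamed class held 33.1% of nuclei in library 2 and 0.420 and 0.318% in libraries 4 and 6. Its share was 18.4% in library 2 with stricter nuclei, and reached 2.59% in library 4 with ATAC clusters and 0.718% in library 6 with doublets kept. Without its nuclei the acinar-like share of library 2 was 68.2%.

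**Figure D1:**
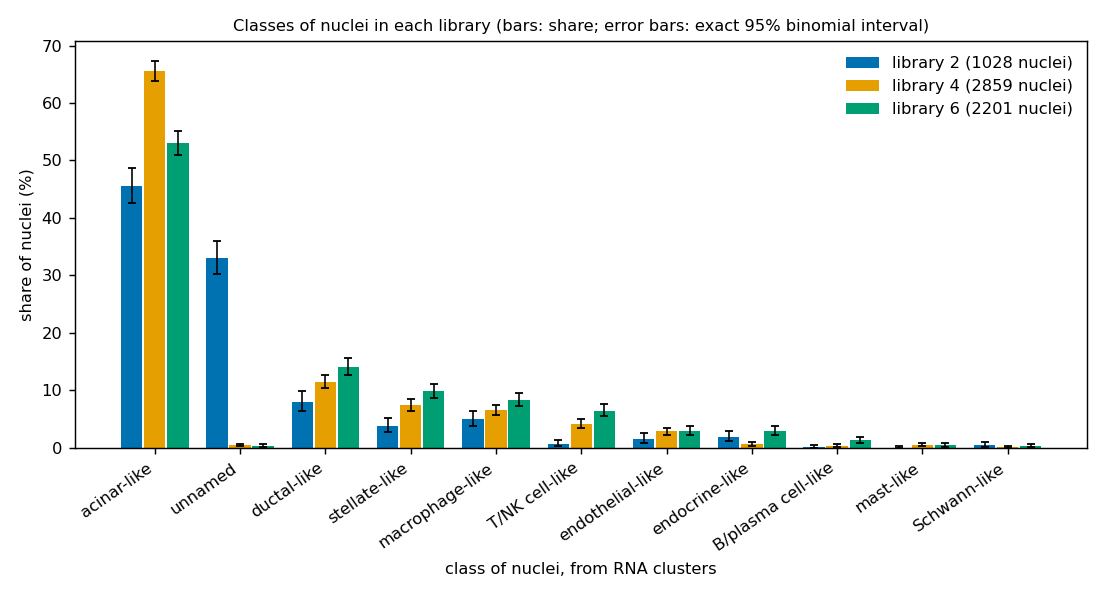
Share of nuclei (%, vertical axis) in each class (horizontal axis) for libraries 2, 4 and 6, with bars for the shares and error bars for the exact 95% binomial intervals. Acinar-like nuclei were the most frequent class in each library, and the unnamed class reached 33.1% in library 2 alone.

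Classes drawn from chromatin and classes drawn from RNA matched in 97.9% of the 5629 nuclei named in both. Acinar-like, ductal-like, stellate-like, endothelial-like, macrophage-like, T/NK cell-like and endocrine-like nuclei each had a chromatin class of their own. B/plasma cell-like and mast-like nuclei had none: 39 of 41 and 23 of 24 fell among T/NK cell-like nuclei by chromatin, and 9 of 11 Schwann-like nuclei among stellate-like nuclei.

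Hormone genes identify the islet cell types: insulin (INS) in beta cells, glucagon (GCG) in alpha cells, somatostatin (SST) in delta cells and pancreatic polypeptide (PPY) in gamma cells. GCG was the hormone seen in most endocrine-like nuclei of libraries 4 and 6, in 13 of 17 nuclei (76.5%, 50.1 to 93.2) and 40 of 64 nuclei (62.5%, 49.5 to 74.3). In acinar-like nuclei, which should lack hormones, GCG was seen in 2 of 1876 and 9 of 1168. In library 2, INS was seen in 14 of 19 nuclei (73.7%, 48.8 to 90.9) of the endocrine-like class and in 30 of 469 nuclei (6.40%, 4.36 to 9.01) of the acinar-like class, and GCG in 5 of 19 and 6 of 469. In libraries 4 and 6, INS was seen in 0 of 17 and 1 of 64 endocrine-like nuclei, and in 0 of 1876 and 1 of 1168 acinar-like nuclei. Median depths were 5100, 5040.0 and 3677.5 UMIs in endocrine-like nuclei and 7228, 4020.5 and 3109 in acinar-like nuclei. SST was seen in 0 of 19, 1 of 17 and 11 of 64 endocrine-like nuclei, and PPY in 0 of 19, 0 of 17 and 0 of 64. Transthyretin (TTR) was seen in 4 of 19, 11 of 17 and 32 of 64, and the beta cell peptide gene IAPP in 9 of 19, 0 of 17 and 0 of 64. Counts of 0 allow up to 15.8, 17.6 and 4.69% of endocrine-like nuclei with a UMI in libraries 2, 4 and 6, at the same limit of 3 counts. Of acinar-like nuclei, SST was seen in 1 of 469, 0 of 1876 and 3 of 1168, TTR in 2 of 469, 4 of 1876 and 8 of 1168 and IAPP in 3 of 469, 0 of 1876 and 0 of 1168. Droplets without a nucleus also carried INS in library 2, at 556 CPM. That may be the source of the INS in acinar-like nuclei there, but whether such droplets hold enough free RNA was not tested. Such droplets carried GCG too, at 95.3, 96.5 and 309 CPM in libraries 2, 4 and 6. In the same order SST was at 27.8, 8.78 and 82.8 CPM and TTR at 11.9, 21.9 and 150 CPM. All 100 endocrine-like nuclei formed 1 cluster, so alpha-like and beta-like nuclei were not compared.

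Acinar cells make and export digestive enzymes, and ductal cells add the bicarbonate-rich fluid that carries them to the gut. Of 12970 genes tested, 1946 were higher and 2255 lower in acinar-like than in ductal-like nuclei (edgeR, donor as a block), with classes drawn from chromatin. Of all calls the share that were higher was 46.3%, and 41.6 to 52.0% over the alternatives. Without library 4 the number of calls was 2433, and without library 6 it was 2761. Values after ± are standard errors for log2 fold changes and SDs over libraries for CPM. The standard errors are the absolute log2 fold change divided by the square root of the quasi-likelihood F statistic. Every gene named was changed in the same direction in 3 of 3 libraries. SPINK1, which encodes the inhibitor that guards against early trypsin activation, was higher in acinar-like nuclei (log2 fold change 3.94 ± 0.28, adjusted p = 2.21e-08), with 2736 ± 319 against 186 ± 58.9 CPM (n = 3 libraries each). GP2, the main membrane protein of zymogen granules, was higher (4.55 ± 0.42, adjusted p = 2.59e-07). REG1A, which may share reads with its near-identical copy REG1B, was higher too (3.99 ± 0.37, adjusted p = 2.62e-07). Digestive enzymes and secretory proteins had 22 of 23 members higher and 0 lower (23 and 0 adjusted over the list alone). Camera gave digestive enzymes and secretory proteins an adjusted p of 2.07e-15, and 0.113 with an estimated correlation. The endoplasmic reticulum (ER) genes that fold and check these proteins followed: XBP1, the transcription factor that expands the secretory ER, was higher (3.92 ± 0.31, adjusted p = 6.53e-08). So was the ER-associated degradation gene SEL1L (3.64 ± 0.33, adjusted p = 2.57e-07). ER stress and unfolded protein response genes had 17 of 19 members higher and 0 lower (19 and 0 adjusted over the list alone). Camera gave ER stress and unfolded protein response an adjusted p of 1.60e-11, and 8.26e-04 with an estimated correlation. Ribosomal protein genes had 5 of 20 members higher and 0 lower (5 and 0 adjusted over the list alone, 2 and 0 with DESeq2), led by RPS2 (1.27 ± 0.31, adjusted p = 0.00447), a call that was lost without library 6 (edgeR adjusted p = 0.176, 5.89e-04 to 0.176 over 16 alternatives). Camera gave ribosomal protein genes an adjusted p of 0.0174, and 0.634 with an estimated correlation.

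Most tested genes of ductal ion and fluid transport were higher in ductal-like nuclei. SLC4A4, the sodium bicarbonate cotransporter that loads ductal cells, was lower in acinar-like nuclei (log2 fold change -7.20 ± 0.42, adjusted p = 3.45e-09). SCTR, the receptor for secretin, was lower too (-6.93 ± 0.60, adjusted p = 2.38e-07, -6.01 without library 4 and -7.78 without library 6), each in 3 of 3 libraries. The ductal ion and fluid transport list had 1 of 14 members higher and 9 lower (1 and 10 adjusted over the list alone). Camera gave ductal ion and fluid transport an adjusted p of 3.40e-05, and 0.0330 with an estimated correlation. Its 1 member higher in acinar-like nuclei was CA12, a membrane carbonic anhydrase (4.21 ± 0.44, adjusted p = 1.23e-06). Among exocrine transcription factors, with 5 of 15 members higher and 8 lower (6 and 8 adjusted over the list alone, 3 and 7 with DESeq2), ONECUT2 was higher in ductal-like nuclei (-6.74 ± 0.52, adjusted p = 7.96e-08). Camera gave exocrine transcription factors an adjusted p of 0.577. MECOM, a zinc finger factor, was higher in acinar-like nuclei (5.23 ± 0.52, adjusted p = 6.52e-07). Members of the extracellular matrix list that were higher in ductal-like nuclei included COL18A1 (-7.73 ± 0.51, adjusted p = 1.06e-08, -6.91 without library 4), COL4A2 (-4.79 ± 0.47, adjusted p = 9.27e-07, -5.84 without library 2) and the laminin chain LAMC1 (-3.10 ± 0.31, adjusted p = 7.15e-07). The extracellular matrix and fibrosis list as a whole had 1 of 25 members higher and 6 lower (1 and 6 adjusted over the list alone). Camera gave extracellular matrix and fibrosis an adjusted p of 0.181.

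Some of the genes that present antigen to T cells were higher in ductal-like than in acinar-like nuclei, each gene named in 3 of 3 libraries. HLA class I genes, whose reads may be shared with near-identical copies, included HLA-B (log2 fold change -2.44 ± 0.38, adjusted p = 7.87e-05) and HLA-C (-2.05 ± 0.37, adjusted p = 3.22e-04). The peptide-loading chaperone TAPBP was also higher there (-1.72 ± 0.26, adjusted p = 6.05e-05). MHC class I antigen presentation had 0 of 13 members higher and 8 lower (0 and 9 adjusted over the list alone). The class I list had a camera adjusted p of 0.00679, and 0.243 with an estimated correlation. Of the class II pathway, which is usual in professional antigen-presenting cells, the invariant chain CD74 (-3.86 ± 0.55, adjusted p = 2.68e-05, -3.08 without library 4) and the protease CTSS, which trims the invariant chain, were higher in ductal-like nuclei (-3.01 ± 0.50, adjusted p = 1.39e-04, -4.09 without library 6). HLA-DPB1 was also higher there (-5.02 ± 0.80, adjusted p = 9.10e-05, -3.54 without library 4 and -6.04 without library 6), a call lost without library 4 (edgeR adjusted p = 0.0752, 1.95e-12 to 0.0752 over 15 alternatives). MHC class II antigen presentation had 0 of 11 members higher and 4 lower (0 and 4 adjusted over the list alone). The class II list had a camera adjusted p of 0.0367, and 0.564 with an estimated correlation. The fixed macrophage markers were at 19.4 ± 17.3 CPM in ductal-like nuclei, 13.9 ± 6.58 CPM in acinar-like nuclei and 4109 ± 70.7 CPM in macrophage-like nuclei. Interferon response genes had 0 of 19 members higher and 7 lower (0 and 7 adjusted over the list alone), with GBP1 (-3.87 ± 0.91, adjusted p = 0.00305), IFI44 (-2.69 ± 0.44, adjusted p = 1.21e-04) and PARP14 (-1.78 ± 0.32, adjusted p = 2.91e-04). Camera gave interferon response an adjusted p of 0.0353, and 0.633 with an estimated correlation.

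Of genes near type 1 diabetes risk loci, 2 of 20 members were higher and 5 lower in acinar-like nuclei (2 and 5 adjusted over the list alone). Over all 12970 genes tested, 1946 were higher and 2255 lower, so the list was called about as often as genes at large. Camera gave type 1 diabetes risk locus genes an adjusted p of 0.367. GLIS3, a transcription factor of islet and duct development, was lower in acinar-like nuclei (-6.09 ± 0.44, adjusted p = 2.59e-08). RASGRP1, a Ras activator known from lymphocytes, was also lower (-3.05 ± 0.48, adjusted p = 8.53e-05). PTPN22, a phosphatase known from T cells, was higher in acinar-like nuclei (2.87 ± 0.47, adjusted p = 1.30e-04, 4.51 without library 6). The hormone secretion machinery list had 3 of 25 members higher and 6 lower (3 and 7 adjusted over the list alone). Camera gave hormone secretion machinery an adjusted p of 0.982. In it the granule protein gene PTPRN2 was higher in acinar-like nuclei (4.49 ± 0.55, adjusted p = 5.47e-06). The calcium channel gene CACNA1D was lower (-4.52 ± 0.57, adjusted p = 1.09e-05, -5.42 without library 2). The incretin receptor GLP1R was higher in acinar-like nuclei by a count ratio of 42.3 (11.6 to 350.2, edgeR adjusted p = 6.03e-05). Islet transcription factors had 1 of 13 members higher and 1 lower (0 and 1 adjusted over the list alone, 0 and 1 with DESeq2), with the homeobox gene MNX1 lower (-2.71 ± 0.34, adjusted p = 7.22e-06). Camera gave islet transcription factors an adjusted p of 0.982. Angiogenesis and endothelial signalling genes had 2 of 17 members higher and 1 lower (2 and 1 adjusted over the list alone), with the adhesion-related sialomucin PODXL higher (3.80 ± 0.51, adjusted p = 1.59e-05, 4.62 without library 6). Camera gave angiogenesis and endothelial signalling an adjusted p of 0.413. Immediate early and stress genes had 5 of 17 members higher and 2 lower (5 and 2 adjusted over the list alone, 2 and 1 with DESeq2), with DUSP1 lower (-3.00 ± 0.48, adjusted p = 9.99e-05). Camera gave immediate early and stress genes an adjusted p of 0.249.

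The largest differences between acinar-like and ductal-like nuclei lay in genes that 1 class barely expressed, in 3 of 3 libraries each. The hexokinase-like gene HKDC1 had no UMI in acinar-like nuclei and was at least 656-fold lower there (edgeR adjusted p = 1.45e-08), with the floor set at 3 counts over the class. The adhesion molecule VCAM1 was lower by a count ratio of 638 (216 to 3109.9, edgeR adjusted p = 1.06e-06), where brackets after a count ratio open with its exact 95% interval. The maltase-glucoamylase relative MGAM2 (log2 fold change -8.56 ± 0.47, adjusted p = 7.34e-09, -7.96 without library 4) and the adenylate cyclase ADCY5 (-8.44 ± 0.59, adjusted p = 9.55e-08, -7.52 without library 4 and -10.06 without library 6) were lower in acinar-like nuclei. In the other direction CFAP97D2 and the exocytosis gene DOC2B had no UMI in ductal-like nuclei and were at least 37.1-fold and 32.9-fold higher in acinar-like nuclei (edgeR adjusted p = 1.05e-05 and 5.70e-06). The receptor phosphatase PTPRT and the potassium channel KCNQ5 were higher by count ratios of 208 (57.4 to 1716, edgeR adjusted p = 1.42e-05) and 125 (34.6 to 1036, edgeR adjusted p = 2.42e-06). PTPRT was a leading gene of an acinar-like cluster with 752 of 944 nuclei from library 4. KCNQ5 led another with 752 of 786 nuclei from library 6, so these pooled ratios may rest mainly on single donors. The chromatin reader CECR2 was higher (log2 fold change 6.23 ± 0.57, adjusted p = 2.50e-07).

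**Figure D2:**
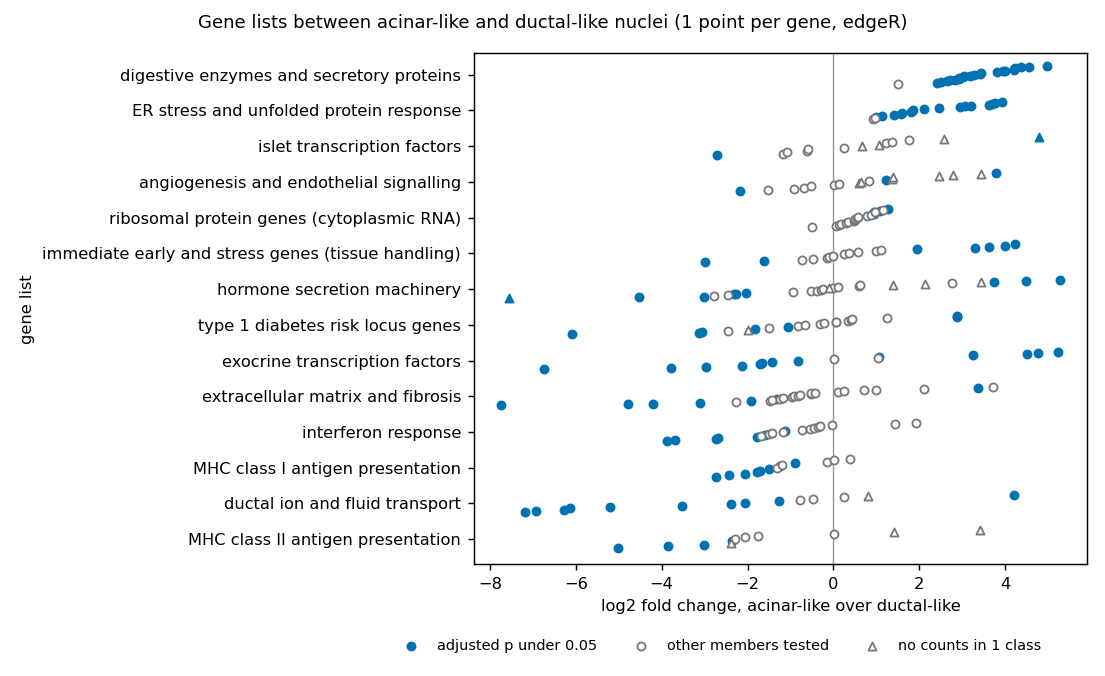
Log2 fold change of each tested member (horizontal axis, acinar-like over ductal-like) in the 14 fixed gene lists (vertical axis), 1 point per gene from edgeR, filled where adjusted p was under 0.05 and triangular where 1 class had no counts. Of the digestive enzyme list 22 members were higher and 0 lower, and of the MHC class I list 0 were higher and 8 lower.

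Chromatin was compared between the same classes. Of 51979 regions tested, 8923 were more and 7495 less accessible in acinar-like than in ductal-like nuclei, with classes drawn from RNA (edgeR), each called region named in the same direction in 3 of 3 libraries. The more accessible made up 54.3%, and 48.1 to 55.4% over the alternatives. Without library 4 the number of calls was 9691. A region at the start of PTF1A (chromosome 10, 23191704 to 23192665), which encodes the acinar transcription factor, was more accessible (log2 fold change 4.98 ± 0.55, adjusted p = 4.01e-12, 58.0 ± 3.82 against 2.30 ± 1.85 CPM, 4.34 without library 6). Regions at the starts of the carboxypeptidase gene CPA1 (chromosome 7, 130379804 to 130380656) and of PRSS1 (chromosome 7, 142748953 to 142749991) were more accessible (3.95 ± 0.43, adjusted p = 3.69e-12, 69.3 ± 8.31 against 5.13 ± 3.15 CPM, and 3.94 ± 0.52, adjusted p = 2.40e-09). Regions at the starts of the chloride channel gene CFTR (chromosome 7, 117479406 to 117480400) and the keratin gene KRT19 (chromosome 17, 41528038 to 41528671) were less accessible (-3.95 ± 0.51, adjusted p = 1.18e-09, 3.78 ± 1.68 against 55.7 ± 3.25 CPM, and -4.17 ± 0.57, adjusted p = 6.19e-09). The RNA of CPA1, PRSS1, CFTR and KRT19 was used to name the classes, so the directions at their starts are no independent support for the names. The start of NKX6-1 (chromosome 4, 84499041 to 84499963), a homeobox gene known from beta cells, was less accessible in acinar-like nuclei (-1.25 ± 0.27, adjusted p = 9.94e-05, 32.1 ± 3.73 against 76.5 ± 7.79 CPM). No difference was detected at the starts of PDX1 (-0.52 ± 0.32, adjusted p = 0.239) and SOX9 (-0.24 ± 0.32, adjusted p = 0.629), the latter with the same direction in 2 of 3 libraries. Among regions away from start sites, 1 lying 1913 bases from the elastase gene CELA2A (chromosome 1, 15453942 to 15454819) was more accessible (6.61 ± 0.75, adjusted p = 1.92e-11, 7.25 without library 2 and 5.79 without library 6). A region inside SDR42E1 (chromosome 16, 82004582 to 82005473) was less accessible (-7.41 ± 0.59, adjusted p = 8.64e-18). Regions within 1 kb of a gene end made up 27.3% of those tested, 16.0% of the more accessible and 18.0% of the less accessible.

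Stellate cells lay down matrix and wrap vessels, and endothelial cells line them. Libraries 4 and 6 held enough nuclei of both classes, and 921 genes were higher and 801 lower in stellate-like than in endothelial-like nuclei of 12970 tested (edgeR). Without library 4 the number of calls was 718 and without library 6 it was 731, where the 1 library left with both classes is assumed to vary like the other classes. The share of calls that were higher was 53.5%, against 42.7% with DESeq2 and 41.7% with library size alone, as the median log2 fold change of all genes moved from 0.25 to 0.005 and 0.05. Genes named had the same direction in 2 of 2 libraries. Count ratios and lower bounds between these classes, in RNA and in chromatin, pool stellate-like sums of libraries 2, 4 and 6. The endothelial-like sums in them come from libraries 4 and 6 alone, so these folds are not within donors. The laminin chain LAMA2 was higher in stellate-like nuclei (log2 fold change 7.90 ± 0.78, adjusted p = 3.28e-06), with 11298 ± 3265 against 54.4 ± 30.1 CPM (n = 3 and 2 libraries). The fibrillar collagen COL5A2 (5.66 ± 0.65, adjusted p = 1.28e-05, 4.44 without library 4 and 13.89 without library 6) and COL6A1 (4.12 ± 0.53, adjusted p = 5.13e-05) were also higher. The extracellular matrix and fibrosis list had 16 of 25 members higher and 0 lower (19 and 0 adjusted over the list alone). Camera gave extracellular matrix and fibrosis an adjusted p of 9.64e-07, and 0.0803 with an estimated correlation. Of its members, 23 to 24 lay above the median of all genes under the 3 scalings. The vascular growth factor receptor KDR was lower by a count ratio of 467 (127 to 3896, edgeR adjusted p = 9.95e-06), a call lost with DESeq2 (adjusted p = 0.336, 2.83e-32 to 0.336 over 16 alternatives). NOTCH4, an arterial Notch receptor, was lower by 152 (50.0 to 757, edgeR adjusted p = 1.59e-05). The angiogenesis and endothelial signalling list had 0 of 17 members higher and 16 lower (0 and 17 adjusted over the list alone, 0 and 9 with DESeq2). Camera gave angiogenesis and endothelial signalling an adjusted p of 7.67e-21, and 1.67e-04 with an estimated correlation. Under each scaling 0 of its members lay above the median of all genes.

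Some antigen presentation genes also differed between these classes, each gene named in 2 of 2 libraries. HLA-E was lower in stellate-like nuclei (-3.23 ± 0.42, adjusted p = 3.97e-05). Also lower were the invariant chain CD74 of the class II pathway (-5.36 ± 0.78, adjusted p = 1.26e-04, -4.51 without library 4 and -6.63 without library 6) and CIITA, the transactivator of class II genes (-3.94 ± 0.68, adjusted p = 6.69e-04). MHC class I antigen presentation had 0 of 13 members higher and 6 lower (0 and 10 adjusted over the list alone). The class I list had a camera adjusted p of 2.45e-06, and 0.0635 with an estimated correlation. MHC class II antigen presentation had 0 of 11 members higher and 4 lower (0 and 7 adjusted over the list alone). The class II list had a camera adjusted p of 4.07e-07, and 0.0967 with an estimated correlation. At most 1 and 0 of their members lay above the median of all genes under the 3 scalings. Macrophage markers were at 124 ± 97.0 CPM in endothelial-like and 33.5 ± 11.4 CPM in stellate-like nuclei. Interferon response genes had 0 of 19 members higher and 1 lower (0 and 1 adjusted over the list alone, 0 and 2 with DESeq2 and with library size alone). Camera gave interferon response an adjusted p of 0.0187, and 0.594 with an estimated correlation. Digestive enzymes and secretory proteins had 0 of 23 members higher and 2 lower (0 and 1 adjusted over the list alone), with acinar markers at 1195 ± 1428 CPM in endothelial-like and 362 ± 168 CPM in stellate-like nuclei. Camera gave digestive enzymes and secretory proteins an adjusted p of 0.0303, and 0.660 with an estimated correlation. The water channel AQP1, a member of the ductal transport list, was lower in stellate-like nuclei (-5.50 ± 0.61, adjusted p = 1.18e-05). Lower too were the exocrine factors MECOM (-3.56 ± 0.53, adjusted p = 1.53e-04) and NR5A2 (-3.09 ± 0.52, adjusted p = 4.98e-04, -4.07 without library 6). The calcium channel CACNA1C, known from smooth muscle, was higher (3.27 ± 0.48, adjusted p = 1.40e-04). The other 8 lists were not called (camera adjusted p from 0.0797 to 0.982). Genes with no UMI in endothelial-like nuclei included GPC6, a glypican, and the mesenchymal homeobox gene PRRX1, at least 103-fold and 50.4-fold higher in stellate-like nuclei (edgeR adjusted p = 8.57e-07 and 3.73e-05). The lysophosphatidic acid receptor LPAR1 was at least 54.8-fold higher (edgeR adjusted p = 1.37e-05). The adhesion receptor ADGRL4 was lower by a count ratio of 2219 (395 to 87889, edgeR adjusted p = 5.44e-07), and CEACAM1 was at least 152-fold lower (edgeR adjusted p = 9.09e-06).

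In chromatin, 5470 regions were more and 2520 less accessible in stellate-like than in endothelial-like nuclei of 51979 tested (edgeR), each named region in 2 of 2 libraries. Without library 4 the number of calls was 2630 and without library 6 it was 4370. The median log2 fold change of all regions was 0.27, and 0.13 with library size alone. Peaks were called per library and not per class, so regions open in the rarer endothelial-like nuclei alone may be missing from those tested. The start of the collagen gene COL1A1 (chromosome 17, 50199983 to 50200937) was more accessible (2.00 ± 0.28, adjusted p = 6.82e-08, 115 ± 17.2 against 28.8 ± 5.80 CPM). The start of the endothelial adhesion gene PECAM1 (chromosome 17, 64390550 to 64391498) was less accessible (-4.92 ± 0.61, adjusted p = 3.94e-09, 2.51 ± 0.465 against 68.1 ± 17.6 CPM). The start of PDGFRB (chromosome 5, 150155384 to 150156341), the growth factor receptor of pericytes and stellate cells, was more accessible (4.52 ± 0.82, adjusted p = 2.55e-05, 55.2 ± 9.60 against 3.09 ± 4.37 CPM, 2.95 without library 4 and 11.42 without library 6), a call lost without library 4 (edgeR adjusted p = 0.0707, 3.66e-10 to 0.0707 over 16 alternatives). A region inside KIAA1671 (chromosome 22, 24985479 to 24986420) was less accessible by a count ratio of 202 (67.8 to 987; edgeR adjusted p = 3.85e-09). A region inside CRYL1 (chromosome 13, 20419624 to 20420674) was at least 36.8-fold more accessible (edgeR adjusted p = 2.37e-07).

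Endocrine cells share an origin with acinar cells but package hormones in regulated granules. The planned floor of 20 nuclei was met by 1 library alone, so endocrine-like and acinar-like nuclei were compared with a floor of 10 nuclei that was chosen after the data were seen. Of 10719 genes tested, 1368 were higher and 1669 lower in endocrine-like nuclei (edgeR). Without library 6 the number of calls was 1549. The share of calls that were higher was 45.0%, against 60.1% with DESeq2 and 55.4% with library size alone, as the median log2 fold change of all genes moved from -0.28 to 0.11 and -0.09. Genes named had the same direction in 3 of 3 libraries. The prohormone convertase PCSK2, which cuts proglucagon and proinsulin, was higher (log2 fold change 11.26 ± 0.68, adjusted p = 2.93e-09, 11.98 without library 2 and 10.68 without library 4). The granule zinc transporter SLC30A8 was higher too (10.32 ± 0.65, adjusted p = 8.07e-10, 12.04 without library 2 and 9.41 without library 4). The exocytosis gene SNAP25 was higher by a count ratio of 3273 (894 to 27227, edgeR adjusted p = 7.41e-10). The calcium channel CACNA1A was also higher (log2 fold change 10.05 ± 0.55, adjusted p = 7.41e-10). The hormone secretion machinery list had 23 of 25 members higher and 0 lower (23 and 0 adjusted over the list alone). Camera gave hormone secretion machinery an adjusted p of 6.59e-29, and 1.67e-04 with an estimated correlation. Islet transcription factors had 11 of 13 members higher and 0 lower (11 and 0 adjusted over the list alone), with ST18 (8.43 ± 0.54, adjusted p = 2.93e-09) and MYT1L (6.94 ± 0.54, adjusted p = 8.53e-08, 7.54 without library 4). Camera gave islet transcription factors an adjusted p of 6.10e-13, and 1.67e-04 with an estimated correlation. Under the 3 scalings 24 to 25 and 13 members of these lists lay above the median of all genes. Type 1 diabetes risk locus genes had 2 of 17 members higher and 3 lower (2 and 4 adjusted over the list alone), with RASGRP1 higher (5.25 ± 0.54, adjusted p = 4.38e-07) and the receptor gene ERBB3 lower (-2.38 ± 0.49, adjusted p = 9.27e-04, -3.11 without library 6). Camera gave type 1 diabetes risk locus genes an adjusted p of 0.982.

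The acinar programme was low in endocrine-like nuclei, each gene in 3 of 3 libraries, with acinar markers at 371 ± 252 CPM there and 11954 ± 5855 CPM in acinar-like nuclei. SPINK1 was lower (log2 fold change -4.55 ± 0.35, adjusted p = 9.24e-09), as was REG1B, subject to its copy REG1A (-4.16 ± 0.44, adjusted p = 5.99e-07). Digestive enzymes and secretory proteins had 0 of 22 members higher and 20 lower (0 and 22 adjusted over the list alone). Camera gave digestive enzymes and secretory proteins an adjusted p of 1.61e-11, and 0.187 with an estimated correlation. Exocrine transcription factors had 0 of 14 members higher and 9 lower (0 and 9 adjusted over the list alone), with MECOM (-4.87 ± 0.70, adjusted p = 2.39e-05, -6.48 without library 2 and -4.27 without library 6) and NR5A2 (-4.34 ± 0.65, adjusted p = 3.46e-05, -5.08 without library 2). Camera gave exocrine transcription factors an adjusted p of 9.99e-05, and 0.0408 with an estimated correlation. ER stress and unfolded protein response genes, which were high in acinar-like nuclei, had 0 of 18 members higher and 14 lower (1 and 14 adjusted over the list alone, 1 and 9 with DESeq2 and with library size alone), with SEL1L (-3.32 ± 0.42, adjusted p = 6.20e-06), HERPUD1 (-3.18 ± 0.46, adjusted p = 2.54e-05) and the sensor kinase EIF2AK3 (-2.33 ± 0.32, adjusted p = 1.38e-05). Camera gave ER stress and unfolded protein response an adjusted p of 8.63e-05, and 0.0732 with an estimated correlation. At most 0, 2 and 1 members of these lists lay above the median of all genes under the 3 scalings. Immediate early and stress genes had 0 of 15 members higher and 6 lower (0 and 7 adjusted over the list alone), with the early factor KLF6 (-3.43 ± 0.60, adjusted p = 1.88e-04, -4.16 without library 2 and -2.72 without library 6). Camera gave immediate early and stress genes an adjusted p of 0.0104, and 0.399 with an estimated correlation. Ribosomal protein genes had 0 of 19 members higher and 4 lower (0 and 3 adjusted over the list alone, 0 and 1 with DESeq2, 0 and 2 with library size alone). Camera gave ribosomal protein genes an adjusted p of 0.0174, and 0.594 with an estimated correlation. The potassium channel KCNQ1 was lower (-4.60 ± 0.62, adjusted p = 1.12e-05). The vasoactive peptide receptor VIPR2 had no UMI in endocrine-like nuclei and was at least 25.9-fold lower (edgeR adjusted p = 2.36e-04). The claudin CLDN10 was at least 23.6-fold lower and the duct and acinar factor ONECUT1 at least 21.3-fold lower (edgeR adjusted p = 2.69e-05 and 4.51e-07). CA12, higher in acinar-like than in ductal-like nuclei, was at least 21.3-fold lower in endocrine-like nuclei (edgeR adjusted p = 1.08e-05).

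Among the genes with the largest endocrine-like excess, the potassium channel subunit KCNMB2 was higher (log2 fold change 10.95 ± 0.61, adjusted p = 3.87e-10, 11.76 without library 2 and 10.15 without library 4). Higher too were the neuronal adhesion gene DSCAM (10.59 ± 0.58, adjusted p = 1.06e-09, 11.51 without library 4) and the syntrophin SNTG1 (10.48 ± 0.60, adjusted p = 1.80e-09, 11.12 without library 2), each in 3 of 3 libraries. FAP, a protease listed here under extracellular matrix and fibrosis and used as a mark of activated fibroblasts, was higher in endocrine-like nuclei (10.74 ± 0.67, adjusted p = 8.07e-10, 9.60 without library 4 and 11.47 without library 6). The ketone body gene HMGCLL1 was higher as well (10.36 ± 0.54, adjusted p = 2.88e-09, 9.54 without library 4). The extracellular matrix list as a whole had 1 of 24 members higher and 0 lower (1 and 0 adjusted over the list alone). Camera gave extracellular matrix and fibrosis an adjusted p of 0.934. The ductal transport list had 2 of 14 members higher and 4 lower (2 and 4 adjusted over the list alone). Camera gave ductal ion and fluid transport an adjusted p of 0.622. SLC5A1, a sodium-glucose transporter in it, was higher in endocrine-like nuclei by a count ratio of 836 (136 to 34368, edgeR adjusted p = 3.85e-05). MHC class I antigen presentation had 1 of 13 members higher and 1 lower (1 and 0 adjusted over the list alone, 1 and 0 with DESeq2 and with library size alone). The class I list had a camera adjusted p of 0.982. MHC class II antigen presentation had 0 of 11 members higher and 0 lower (0 and 0 adjusted over the list alone, 1 and 0 with DESeq2). The class II list had a camera adjusted p of 0.982. Interferon response genes had 0 of 14 members higher and 0 lower (0 and 0 adjusted over the list alone). Camera gave interferon response an adjusted p of 0.282. Angiogenesis genes had 1 of 16 members higher and 2 lower (1 and 2 adjusted over the list alone, 2 and 2 with DESeq2). Camera gave angiogenesis and endothelial signalling an adjusted p of 0.982.

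**Figure D3:**
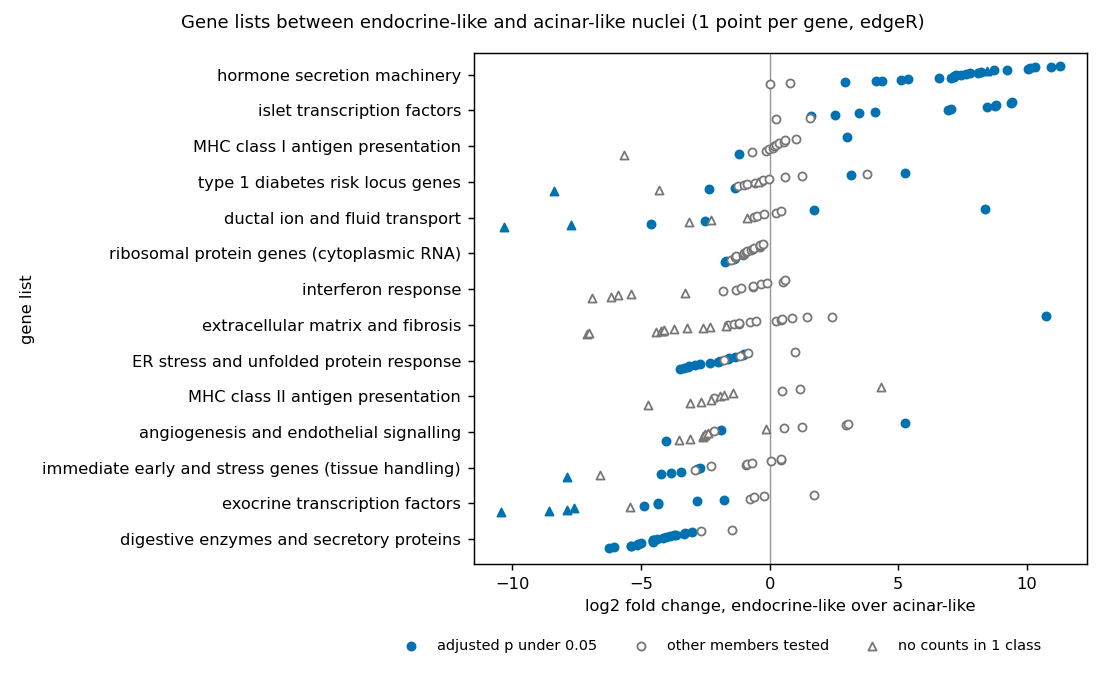
Log2 fold change of each tested member (horizontal axis, endocrine-like over acinar-like) in the 14 fixed gene lists (vertical axis), 1 point per gene from edgeR, filled where adjusted p was under 0.05 and triangular where 1 class had no counts. Hormone secretion genes had 23 members higher and 0 lower, and digestive enzymes 0 higher and 20 lower.

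In chromatin, 2656 regions were more and 10186 less accessible in endocrine-like than in acinar-like nuclei of 50786 tested (edgeR), each named region in 3 of 3 libraries. Without library 4 the number of calls was 7008 and without library 6 it was 5122. Of the calls 20.7% were gains, against 36.5% with DESeq2 and 36.8% with library size alone, as the median log2 fold change of all regions moved from -0.50 to -0.25 and -0.14. Tested regions had a peak in each of libraries 2, 4 and 6, called per library and not per class. Endocrine-like nuclei made up 1.85, 0.595 and 2.91% of nuclei there, so regions open in them alone may be missing. The balance of gains and losses therefore does not describe all their chromatin. The start of PTF1A (chromosome 10, 23191704 to 23192665) was less accessible (-4.39 ± 0.79, adjusted p = 1.42e-06, 3.99 ± 3.63 against 62.1 ± 4.22 CPM, -5.12 without library 4 and -3.35 without library 6). That of CPA1 was less accessible too (chromosome 7, 130379804 to 130380656; -3.14 ± 0.59, adjusted p = 4.87e-06, 6.13 ± 10.6 against 74.2 ± 9.11 CPM, -2.50 without library 2 and -11.14 without library 6). The start of PRSS1 (chromosome 7, 142748953 to 142749991) had no counts in endocrine-like nuclei and was at least 20.7-fold less accessible (edgeR adjusted p = 1.10e-08). The start of the progenitor factor SOX9 (chromosome 17, 72120470 to 72121375) was less accessible (-2.24 ± 0.52, adjusted p = 3.05e-04, 10.8 ± 3.81 against 54.1 ± 7.56 CPM). NKX6-1 (chromosome 4, 84499041 to 84499963) was more accessible at its start (0.97 ± 0.36, adjusted p = 0.0298, 67.7 ± 12.0 against 34.4 ± 4.07 CPM), a call lost without library 4 or library 6 (edgeR adjusted p = 0.179 and 0.196, 6.80e-04 to 0.196 over 14 alternatives). A region 319764 bases from the nearest protein-coding gene, ZC3H12C (chromosome 11, 109772635 to 109773628), was more accessible (7.96 ± 1.16, adjusted p = 1.30e-09, 45.2 ± 8.57 against 0.174 ± 0.133 CPM). So was 1 lying 361165 bases from CENPC (chromosome 4, 67106681 to 67107597; 7.65 ± 1.11, adjusted p = 1.21e-09). A region inside NKD1 (chromosome 16, 50591739 to 50592657) was at least 34.6-fold less accessible (edgeR adjusted p = 6.01e-19). The starts of INS, GCG and SST held no tested region.

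Accessibility at gene ends and RNA tended to move together across genes. Spearman's rho between the ATAC and RNA log2 fold changes was 0.510 over 10095 genes for acinar-like against ductal-like nuclei, 0.351 over 10095 for stellate-like against endothelial-like nuclei and 0.439 over 8653 for endocrine-like against acinar-like nuclei. These correlations run across genes, which are not independent replicates. Within single libraries rho ranged from 0.359 to 0.496, from 0.259 to 0.300 and from 0.263 to 0.393. Of 1088 genes called in both modalities between acinar-like and ductal-like nuclei, 1043 moved the same way and 45 the opposite way. The counts were 382 and 8 of 390 between stellate-like and endothelial-like nuclei, and 672 and 30 of 702 between endocrine-like and acinar-like nuclei. PRICKLE2, a planar polarity gene singled out after its values were seen, had more RNA (log2 fold change 1.81) and a less accessible region at a gene end (-2.62; chromosome 3, 64267679 to 64268610) in acinar-like than in ductal-like nuclei.

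The peak lists of all 8 libraries were used to ask whether peaks found in every donor lie nearer to genes than peaks found in a single donor. Among peaks that every other list also held, 28.4% on average lay within 1 kb of an end of a protein-coding gene. These peaks mark nearly the same regions in all 8 lists, so their share is in effect a single value. Among peaks found in that library alone the share was 5.16% ± 1.38 (SD, n = 8 libraries). The difference was 23.3 ± 1.38 percentage points and ranged from 20.1 to 24.2, above 0 in 8 of 8 libraries (exact sign-flip permutation test, 2-sided p = 0.00781, the smallest that 8 libraries allow). The test treats the 8 differences as independent although they share that set, so their spread comes almost only from the private peaks. The labels name the ATAC part of library 7 in a pair of ways, and 1 of the names is also that of library 6. Its list was counted as a separate donor, which adds a doubt to n = 8, although the lists of libraries 6 and 7 differ, with 96853 and 118650 autosomal peaks. Shared peaks numbered 48372 to 48401 per library and private peaks 1360 to 8673. The test did not match peaks for strength. When only the strongest 61953 peaks of libraries 4 and 6 were kept, the share near a gene end rose to 24.95 and 25.03%. It was 16.0 and 17.5% in the full lists, and the share found in every other list rose as well. The difference therefore cannot be told apart from one between strong and weak peaks.

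**Figure D4:**
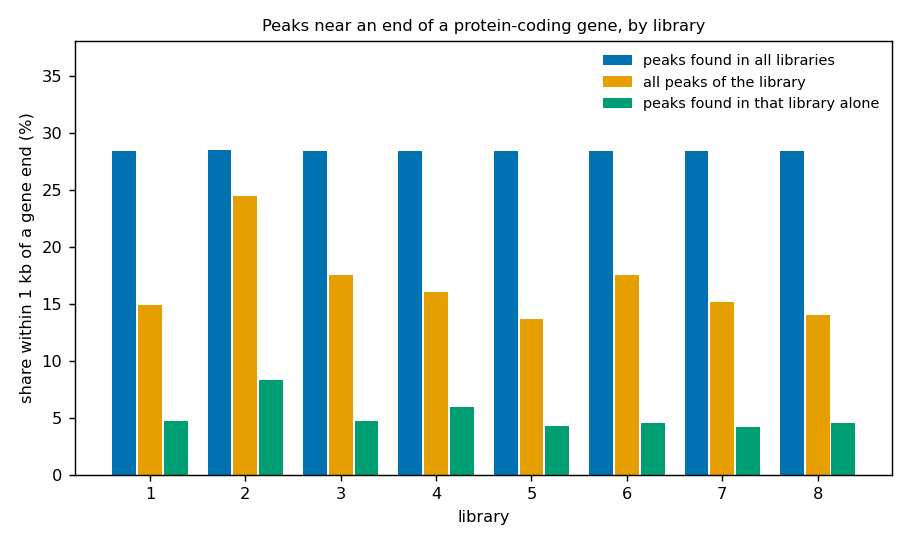
Share of peaks within 1 kb of an end of a protein-coding gene (%, vertical axis) in each of the 8 libraries (horizontal axis), with 1 bar each for peaks found in all libraries, all peaks of the library and peaks found in that library alone. Peaks found in all libraries averaged 28.4%, and in library 2 the share of all peaks was 24.4%.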

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

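No test in this part was chosen after the result it measures was seen, although both patterns were found in these data. No biological explanation was tested, because the design holds a single group of donors.

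The peak list of library 2 stood apart from those of the 7 other libraries in 4 of 9 measures compared between lists, and chance sets a library apart in about 1 in 20 such groups. The measures are related, since all come from the same list. Of its peaks, 24.4% lay within 1 kb of a gene end, against 13.7 to 17.5% in the others, and 78.1% were found in every other list, against 35.2 to 50.0%. Its private peaks lay near a gene end in 8.31% of cases, against 4.21 to 5.97%, and its difference between shared and private peaks was 20.1 percentage points, against 22.5 to 24.2. Library 2 had 61953 autosomal peaks, the fewest of the 8 lists (96853 to 137253 in the others), and the lowest ATAC total of the 3 libraries with counts. The number of peaks was not among the 4 measures that stood apart.

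A candidate explanation is that fewer, stronger peaks were called at lower depth, since strong peaks gather at gene starts. The peaks of libraries 4 and 6 were ranked by counts and the strongest 61953 were kept. Their share near a gene end then averaged 25.0% (24.95 and 25.03), from 16.0 and 17.5% in the full lists. A list of fewer, stronger peaks would thus give the share near gene ends seen in library 2. Depth itself was not changed, so the test cannot tell lower depth from another cause of a short list. The share found in every other list rose to 71.1% (71.0 and 71.3) from 44.0 and 50.0%, but this measure decides nothing about depth. Every list held nearly the same number of shared peaks (48372 to 48401), so the share follows the length of a list, and 61953 peaks of either library stay at or under the 78.1% of library 2. The measures of private peaks were not tested in this way.

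INS, the insulin gene, appeared outside the endocrine-like class in library 2. A cluster of 340 nuclei of this library, left unnamed because its 10 leading genes held 1 marker of another class and 0 of the acinar list that scored best, carried INS at 367 CPM, against 12.0 CPM in acinar-like and 1836 CPM in endocrine-like nuclei. Barcodes with 5 to 50 UMIs carried it at 556 CPM, against 0 in libraries 4 and 6, where 3 counts would be 13.2 and 9.55 CPM. INS was seen in 116 of the 340 nuclei (34.1%), against 6.40% of acinar-like nuclei, although the cluster was shallower, with a median of 1499.5 UMIs and 1860.5 ATAC counts against 7228 and 14953 in acinar-like nuclei.

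Free RNA and mixed nuclei were weighed as sources for this cluster. Free RNA of library 2 should raise INS and the markers of other classes in 1 ratio, and the INS ratio was 1.02 (0.437 to 2.28) times the median ratio of the ductal, stellate, macrophage and alpha markers. The ratio was not equal between lists, however: the excess over acinar-like nuclei was 65.2% of that in free RNA for INS, against 92.1% for ductal, 79.8% for macrophage, 47.9% for stellate and 23.9% for alpha markers. INS lay within that range, and the reason for the lower alpha value was not tested. Brackets in this paragraph are 95% bootstrap intervals over the nuclei of library 2, from 1000 draws. Beta nuclei mixed with acinar nuclei were modelled on the 19 endocrine-like nuclei of library 2, of which 14 had INS. Such nuclei would need a share of 19.5% of the cluster and would bring the other genes of hormone secretion. Those genes reached 0.156 (0.0697 to 0.384) of the excess needed. This argues against nuclei of that make-up as the whole source, though not against purer beta nuclei. The free RNA ratios compare shares of RNA, not the amount of free RNA in a droplet. In library 2 the barcodes of free RNA held 140 INS UMIs over 21743 barcodes, against 249 over the 340 nuclei. This argues against free RNA as the source at the amount held by those barcodes. Whether droplets of the cluster held far more free RNA was not tested. The unequal ratios leave open whether such an amount would be the whole source, and what would release that RNA stays open too.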

How the results depend on the processing

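Tests chosen only after the data were seen are those of endocrine-like nuclei with a floor of 10 nuclei, of macrophage-like against stellate-like nuclei, of endothelial-like nuclei with at least 10 nuclei, of shares without the unnamed class, and of other splits of the sums.

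With each of the 3 libraries left out in turn, the RNA calls numbered 2433 to 3499 (from 4201) between acinar-like and ductal-like nuclei, 718 to 1579 (from 1722) between stellate-like and endothelial-like, 1549 to 2508 (from 3037) between endocrine-like and acinar-like, and 2674 to 3378 (from 4218) between macrophage-like and stellate-like nuclei. In ATAC they numbered 9691 to 14185 (from 16418), 2630 to 7628 (from 7990), 5122 to 9291 (from 12842) and 10062 to 12638 (from 14541) in the same order. Stellate-like and endothelial-like nuclei without library 4 or 6 rest on 1 library with both classes, which is assumed to vary like the other classes. Fewer samples are part of the construction of these alternatives. Of all 123 counts of calls under alternatives, 111 stayed within 1.5 times the reported count, and the 12 others came from leaving out a library.

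Of 26 gene list calls made by camera with a preset correlation, 7 held with an estimated correlation. These were hormone secretion machinery, islet transcription factors and exocrine transcription factors between endocrine-like and acinar-like nuclei, the ER stress and unfolded protein response and ductal ion and fluid transport between acinar-like and ductal-like, angiogenesis between stellate-like and endothelial-like, and extracellular matrix between macrophage-like and stellate-like nuclei. The estimate rises with correlation between members, which is high in lists such as the digestive enzymes. Fry, which asks whether members change at all, lost fewer calls. Between acinar-like and ductal-like nuclei, digestive enzymes (fry adjusted p = 2.03e-04), MHC class I (0.00205) and class II (0.0427) kept their call. Interferon response (0.0880) and ribosomal protein genes (0.158) lost it. Over both alternatives, 27 of 52 values kept the call and 25 lost it.

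Spearman's rho of accessibility and RNA rose where only genes called in either modality were used, to 0.698 between acinar-like and ductal-like, 0.663 between stellate-like and endothelial-like, 0.630 between endocrine-like and acinar-like and 0.687 between macrophage-like and stellate-like nuclei. That alternative keeps the genes with the larger changes. The 8 other values of rho moved by less than the spread between libraries. The difference between shared and private peaks was 23.2 percentage points with reciprocal overlap, 23.9 within 5 kb and 23.2 for peaks of at least 500 bases.

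Class shares moved beyond their binomial intervals in 17 of 153 cases. With stricter nuclei, library 2 held 56.7% acinar-like, 9.96% ductal-like and 18.4% unnamed nuclei, and library 6 held 55.5% acinar-like, 5.01% T/NK cell-like and 0.155% mast-like nuclei. Without the unnamed class library 2 held 68.2% acinar-like, 11.9% ductal-like, 7.41% macrophage-like and 5.67% stellate-like nuclei, because fewer nuclei were counted. With ATAC clusters library 4 held 63.4% acinar-like, 5.11% T/NK cell-like and 2.59% unnamed nuclei, and library 6 held 8.04% T/NK cell-like and 0.682% unnamed. With doublets kept, library 6 held 50.7% acinar-like and 0.718% unnamed nuclei. The T/NK cell-like class gained by ATAC clusters because B/plasma cell-like and mast-like nuclei have no chromatin class and 39 of 41 and 23 of 24 fell among T/NK cell-like nuclei. The causes of the other moves were not tested, apart from the removal of the unnamed class.

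Named genes and regions gave 3746 values under alternatives. Of these, 3582 kept the direction and the call, 163 kept the direction and lost the call, and 1 reversed. SLC4A4, the ductal bicarbonate cotransporter, changed to a log2 fold change of -0.90 between macrophage-like and stellate-like nuclei with classes from RNA clusters (adjusted p = 0.468), and the cause was not tested. Calls were lost most often without library 4 (34), without library 6 (28) and with DESeq2 (24). Without the replicate block, which is part of the design because the classes share donors, 16 of 243 named items lost their call and no count of calls moved by more than 1.5 times.

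Not run were clusters of each library alone for RNA between stellate-like and endothelial-like nuclei, and at least 50 nuclei for endocrine-like nuclei in RNA and ATAC, because fewer than 2 libraries then hold both classes.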

Other observations

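The comparison of macrophage-like with stellate-like nuclei and the splits of the sums were chosen only after the data were seen, and the tests of the MHC class II pattern were chosen before their results were seen.

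Macrophages and stellate cells are the immune and matrix-producing cells of the pancreas stroma, and each class held more nuclei than the endothelial-like class. Of 12970 genes tested, 1912 were higher and 2306 lower in macrophage-like than in stellate-like nuclei (edgeR), and genes named had the same direction in 3 of 3 libraries. The share of calls that were higher was 45.3%, and 43.3 to 52.8% over the alternatives, the highest with library size alone. Without library 4 the number of calls was 2674 and without library 6 it was 2744. Every tested member of MHC class II antigen presentation was higher in macrophage-like nuclei, with 11 of 11 members higher and 0 lower (11 and 0 adjusted over the list alone). The class II list had a camera adjusted p of 6.88e-10, and 0.0617 with an estimated correlation. CIITA, the transactivator of the class II genes, was higher (log2 fold change 5.88 ± 0.53, adjusted p = 2.32e-07). Higher as well were CD74 (6.08 ± 0.65, adjusted p = 1.32e-06) and the protease CTSS (6.06 ± 0.59, adjusted p = 4.83e-07, 6.95 without library 6). MHC class I antigen presentation had 6 of 13 members higher and 0 lower (6 and 0 adjusted over the list alone), led by HLA-E (2.08 ± 0.38, adjusted p = 3.49e-04) and the class I transactivator NLRC5 (1.86 ± 0.38, adjusted p = 0.00101). The class I list had a camera adjusted p of 0.00607, and 0.243 with an estimated correlation. Interferon response genes had 7 of 19 members higher and 0 lower (7 and 0 adjusted over the list alone), with PARP14 higher (1.51 ± 0.32, adjusted p = 0.00144). Camera gave interferon response an adjusted p of 0.0174, and 0.594 with an estimated correlation. Genes with no UMI in stellate-like nuclei included the integrin ITGAM, the costimulatory molecule CD86 and LAPTM5, at least 149-fold, 127-fold and 88.4-fold higher (edgeR adjusted p = 2.82e-07, 4.89e-07 and 2.44e-07).

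Stellate-like nuclei carried the matrix. The extracellular matrix and fibrosis list had 0 of 25 members higher and 21 lower (0 and 21 adjusted over the list alone), with the fibrillin FBN1 and the collagen COL15A1 at least 411-fold and 335-fold lower in macrophage-like nuclei, where they had no UMI (edgeR adjusted p = 1.89e-08 and 1.07e-06). Camera gave extracellular matrix and fibrosis an adjusted p of 4.30e-14, and 0.0194 with an estimated correlation. The cadherin CDH11, known from synovial and other fibroblasts, was at least 423-fold lower (edgeR adjusted p = 6.70e-07), and the laminin chain LAMC1 was also lower (log2 fold change -5.57 ± 0.38, adjusted p = 2.76e-08). Genes near type 1 diabetes risk loci had 10 of 20 members higher and 3 lower (10 and 3 adjusted over the list alone), with the lymphoid and myeloid factor IKZF1 (6.39 ± 0.55, adjusted p = 2.32e-07, 7.90 without library 4) and the adaptor SH2B3 (2.72 ± 0.28, adjusted p = 8.99e-07) higher and BACH2 lower (-2.79 ± 0.29, adjusted p = 1.06e-06). Camera gave type 1 diabetes risk locus genes an adjusted p of 0.0483, and 0.163 with an estimated correlation. Digestive enzymes and secretory proteins had 7 of 23 members higher and 0 lower (7 and 0 adjusted over the list alone), with acinar markers at 898 ± 798 CPM in macrophage-like and 362 ± 168 CPM in stellate-like nuclei. Camera gave digestive enzymes and secretory proteins an adjusted p of 0.0155, and 0.633 with an estimated correlation. The other 8 lists were not called (camera adjusted p from 0.0560 to 0.982). In chromatin, 6413 regions were more and 8128 less accessible of 51979 tested (edgeR), a share more accessible of 44.1%, and 39.9 to 50.3% over the alternatives, with the start of PDGFRB (chromosome 5, 150155384 to 150156341) less accessible (-3.60 ± 0.57, adjusted p = 3.07e-07) in 3 of 3 libraries. Spearman's rho of accessibility and RNA was 0.506 across 10095 genes.

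Acinar-like nuclei fell into 6 clusters that libraries shared unevenly. A cluster led by REG3A and the metallothionein genes MT1G and MT1H held 786 nuclei, 752 of them from library 6. A cluster led by FGL1 and PTPRD held 130 nuclei, 123 of them from library 2, with a median of 10973.5 UMIs. A cluster led by the protease and lipase genes CTRL, CELA2A and CEL held 819 nuclei, 697 of them from library 4. These leading genes were read from the clusters after they were formed, and the uneven shares are values of single donors.

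The class II genes that were higher in ductal-like than in acinar-like nuclei, CTSS, CD74, HLA-DPB1 and CIITA, were set against 2 technical sources. Macrophage nuclei or their RNA would have to make up 16.5, 10.2 and 6.29% of the ductal-like sums of libraries 2, 4 and 6 and would raise the macrophage markers with them. The markers reached 0.00218 of the excess needed (-0.0349 to 0.0324 over the 3 libraries), which argues against macrophages as the source. After expected free RNA was subtracted, the median log2 fold change of the 4 genes was -4.00, from -3.44 with a median standard error of 0.52, and 4 of 4 were still called (highest edgeR adjusted p = 0.00221), which argues against free RNA. HLA-DPB1 may share reads with related HLA genes, and other antigen-presenting cells such as dendritic cells were not tested. No biological explanation is given by the design, so a class II programme of ductal cells is a hypothesis that was not tested here.

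For comparisons with 3 sums per class, the sums were also split in the 9 other ways that 3 against 3 allow, in fits of the 6 sums alone. With 10 splits the share as large as the real result can never fall under 0.05, and in each comparison only 1 of 10, the real split itself, reached the real number of calls. Each donor gave 1 sum per class, and only 4 of the 10 splits, the real one included, part the sums of every donor. The others keep sums of a donor together, so among splits that respect the pairing the number was 1 of 4, which is also too few for a share under 0.05. The real numbers of RNA calls were 4642 between acinar-like and ductal-like, 2616 between endocrine-like and acinar-like and 2867 between macrophage-like and stellate-like nuclei, and the highest of the other splits was 0. In ATAC they were 20052, 9042 and 12131, and the highest of the other splits was again 0.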
